A study of Sus scrofa with 6 samples.

How the data were processed

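Gene counts were analysed for 6 libraries of pig (Sus scrofa) oviduct ampulla, 3 labelled post-ovulatory and 3 labelled early luteal. Per the labels' protocols, total RNA from ampulla tissue was made into stranded libraries of polyadenylated RNA with a KAPA kit and read in pairs on an Illumina NextSeq2000. Per the submitters' processing notes, FastQC 0.11.4, Trim Galore, STAR and the genome build Sscrofa11.1 were used. The counting tool, its strand setting and the annotation release are not given in the sources used here, so genes that overlap, lie antisense to each other or have near-identical copies are uncertain where the counting could split their reads. The authors deposited 1 table of whole-number counts per Ensembl gene, with 6 columns of samples and no normalization. The header of that table lacks a tab after its first word, so columns were taken by position and matched to samples by the order of the header words. The word for early luteal replicate 3 drops a letter of that sample's label and matches no other sample. No column of values was left unused.

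The table holds 35670 genes, of which 5622 had no count in any library. Gene symbols came from a table that pairs Ensembl identifiers with symbols, and 15623 identifiers had one. PAX8 and MKI67 had no row with their symbol and were not analysed here. Library totals ran from 7370723 to 30954222 counts. A count of 3, taken as the floor of each library, corresponded to 0.0959 CPM (counts over the scaled library total, times 1e6) in the deepest library and 0.406 CPM at most. Intervals and floors of this kind cover counting error only. CPM values were computed from the counts with TMM scaling.

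The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust estimates) with TMM scaling and the filterByExpr filter, which left 17920 genes, 12783 of them with a symbol. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Fold changes are early luteal over post-ovulatory, and their SE was taken as the absolute log2 fold change over the square root of the F statistic. The common biological coefficient of variation was 0.485. No source says that the replicates of a stage came from separate animals, so p-values measure the spread between these samples, which may be technical.

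In the same way 51 gene lists were fixed beforehand: processes, quality measures and markers of the cell types that the tissue could hold. Of their 1222 genes, 1080 had a row. The 45 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), again with the correlation estimated from the data, and with fry. Camera asks whether a list moved more than the other genes. The directional p of fry asks whether the genes of a list moved, on balance, one way, and its mixed p whether they changed in either direction. A list score is the mean over members of log2 CPM (prior count 2), centred per gene over the 6 libraries. Principal components and correlations between libraries used log2 CPM with the same prior count.

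Named genes were chosen by a rule fixed in advance. Because no gene passed the threshold, its part 1 takes the 10 genes with a symbol and the lowest unadjusted p, given as not past the threshold; 1 of them is not reported here. Its part 2 is a fixed panel (OVGP1, PGR, ESR1, FOXJ1, PAX8, OXTR, PTGS2, IGF1, HSPA5 and MKI67). Its part 3 takes, for a list that is described, up to 4 members with the lowest p and, as none passed, up to 2 with the highest mean CPM, read as an addition to the 4. Genes of the multiciliation test in the closing section were chosen after the cell cycle values, and the score of the ciliogenesis list that holds them, had been seen.

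The scripts were tested on simulated data for this comparison, drawn with the means and library sizes of the 6 libraries. Counts were drawn for the 17920 tested genes, and 17355 of them passed the filter on the simulated counts. The edgeR test recovered 2 of 50 genes changed 2-fold, 17 of 50 changed 4-fold, 31 of 50 changed 8-fold and 42 of 50 changed 16-fold, and called 8 of 17136 unchanged genes. Camera called the simulated list of 27 genes changed 2-fold and 0 of 44 unchanged lists. Each gene was drawn independently of the others. The simulation therefore does not show how often camera calls unchanged lists whose genes vary together. In the data the estimated correlation was 0.39 for cholesterol and lipid synthesis, 0.83 for cell cycle and -0.007 for oestrogen response.

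Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling and library totals alone; no filter on low counts and a filter of 1 CPM in 3 libraries; the replicate number as a block; each library left out in turn; DESeq2 1.42.0, limma voom and limma voom with sample quality weights; thresholds of 0.01 and 0.1; and glmTreat against a 2-fold change. A fit on genes with a symbol alone and one without robust estimates were added after seeing the data. Genomic spans for 1 check came from a RefSeq gene table of the same build, matched by symbol. GC content was not analysed here.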

Results

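The ampulla is the segment of the oviduct in which fertilisation takes place. Messenger RNA was counted in ampulla tissue of pigs at 2 stages of the cycle, with 3 libraries from the post-ovulatory stage and 3 from the early luteal stage, when the corpora lutea form and progesterone increases. Post-ovulatory replicates 1, 2 and 3 held 14716272, 7370723 and 30954222 counts. Early luteal replicates 1, 2 and 3 held 14056141, 8342520 and 14785020. Between 21658 genes (early luteal replicate 2) and 26524 genes (post-ovulatory replicate 3) had at least 1 count. The only comparison that the design holds is early luteal against post-ovulatory tissue.

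Genes of cholesterol and lipid synthesis were lower in the early luteal ampulla, together with the progesterone receptor PGR and the growth factor IGF1, while genes induced by progesterone and glucocorticoids were higher. These list calls were made by limma camera at a preset correlation, and 0 of the 45 lists tested passed with an estimated correlation (3 at an unadjusted p under 0.05). The sterol genes formed the clearest group: all 3 early luteal list scores (-0.40, -1.36 and -0.52) lay below all 3 post-ovulatory ones (0.98, 0.41 and 0.88). The stages lay closer in the progesterone and glucocorticoid list, where early luteal replicate 2 scored -0.018 and post-ovulatory replicate 2 -0.058, and immediate early genes, a list that responds to tissue handling, rose as well (median log2 fold change 0.53; limma camera, adjusted p = 0.0117). Endoplasmic reticulum chaperones and collagen genes were lower as well, by the same preset correlation. These are results on lists of genes, and no single gene passed the threshold: edgeR's quasi-likelihood test called 0 of 17920 genes, the lowest Benjamini-Hochberg adjusted p being 0.108. At an unadjusted p under 0.05 it counted 1275 genes, 640 higher and 635 lower in early luteal tissue, where chance alone gives 896. By the other tools, limma voom called 0 genes (1277 at an unadjusted p under 0.05), limma voom with sample quality weights called 9, and DESeq2 called 175, of which 83 were higher and 92 lower. Of the DESeq2 calls, 168 were also tested by edgeR, all with an unadjusted p under 0.05 there, and in 160 of them the stages did not overlap. Over all tested genes 17.2% did not overlap, where chance gives 10%. The DESeq2 calls were made on the same libraries, so their low edgeR p and lack of overlap are no separate support for them.

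Early luteal replicate 2 stood apart from the other libraries of both stages. The first principal component held 55.9% of the variance and set early luteal replicate 2 (176) apart from the other 5 libraries (-51.0 to 2.39). The second held 18.3% and placed post-ovulatory replicate 1 at 85.1, with the others between -68.2 and 17.1. The median Pearson correlation across genes was 0.937 between post-ovulatory libraries, 0.865 between early luteal libraries and 0.916 between libraries of different stages. Early luteal replicates 1 and 3 correlated at 0.921, and each of them with early luteal replicate 2 at 0.822 and 0.865.

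**Figure D1:**
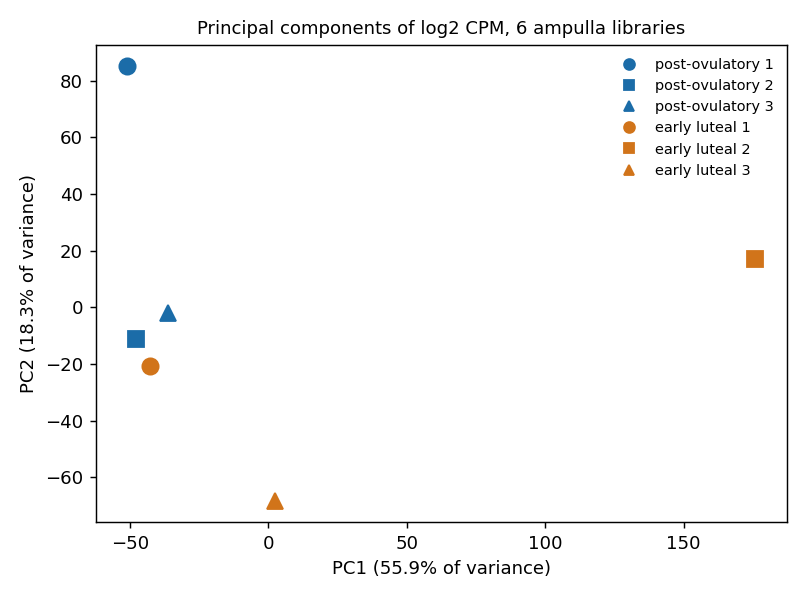
First and second principal components of log2 CPM for the 6 libraries, with 55.9% and 18.3% of the variance on the axes; colours mark the stage and symbols the replicate. Early luteal replicate 2 lies alone on the right at 176 and post-ovulatory replicate 1 alone at the top at 85.1.

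Among the 10 genes with a symbol and the lowest unadjusted p were SQLE, FGFBP1, PGR, CYP51A1, PON3, IGF1, HYOU1, APOD and VASH1. In each of them the 3 libraries of one stage lay above the 3 of the other. Each missed the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p from 0.216 for SQLE to 0.441 for VASH1) and passed it in DESeq2 (adjusted p from 8.11e-10 for SQLE to 0.000364 for HYOU1). FGFBP1, a secreted carrier of fibroblast growth factors, stood at 15.2 ± 5.53 CPM (SD, n = 3) in early luteal and 115 ± 66.0 CPM in post-ovulatory tissue. PON3, a paraoxonase, stood at 12.9 ± 3.25 against 84.1 ± 43.8 CPM, and VASH1, an inhibitor of angiogenesis, at 8.28 ± 3.82 against 38.2 ± 2.30 CPM. APOD, an apolipoprotein that carries small hydrophobic molecules, was the only one of these with the higher level in early luteal tissue, at 132 ± 33.6 against 30.8 ± 11.3 CPM (log2 fold change 2.10 ± 0.36, SE).

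The lowest p-values of all belonged to genes without a symbol in the table used. ENSSSCG00000009240 stood at 39.5 ± 5.58 CPM in early luteal and 3.34 ± 0.915 CPM in post-ovulatory tissue, and ENSSSCG00000002749 at 59.8 ± 16.1 against 4.23 ± 1.77 CPM; both had an adjusted p of 0.108 in edgeR's quasi-likelihood test. In the other direction, ENSSSCG00000057692 stood at 19.6 ± 7.12 against 118 ± 38.8 CPM and ENSSSCG00000060025 at 2.16 ± 0.590 against 30.6 ± 16.8 CPM (adjusted p = 0.333 for both, edgeR).

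**Figure D2:**
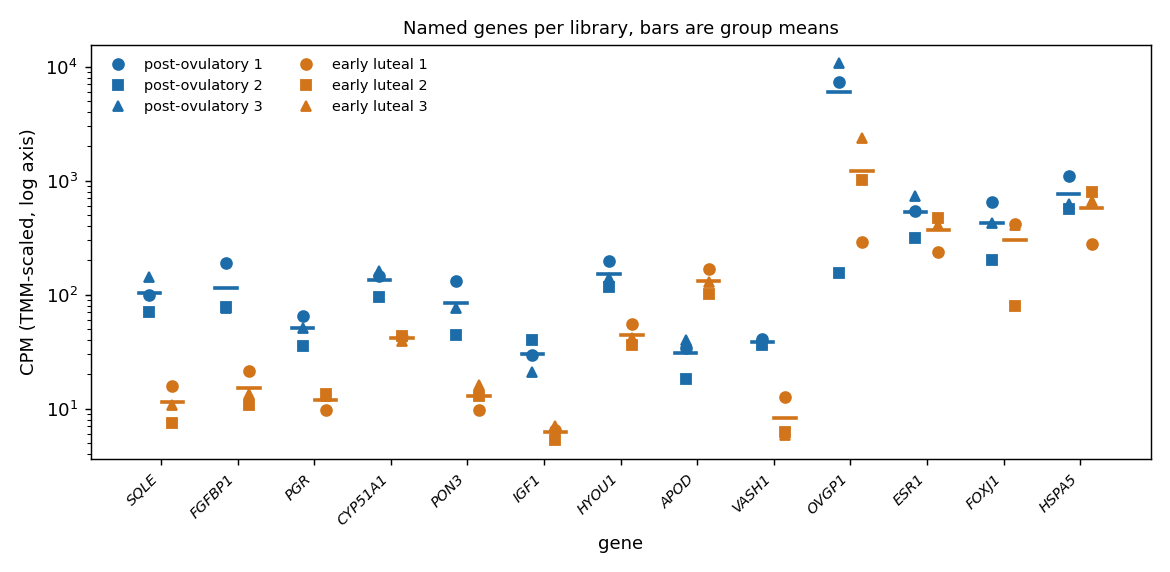
CPM (log axis) of named genes in each library, post-ovulatory in blue and early luteal in orange, symbols marking the replicate and bars the group means. For the genes from SQLE to VASH1, the stages do not overlap, whereas OVGP1 ranges from 156 to 10688 CPM within the post-ovulatory stage.

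Of 45 gene lists tested, 15 passed the threshold with limma camera at a preset correlation, 13 lower and 2 higher in early luteal tissue. With an estimated correlation 0 passed, and 3 (oestrogen response, cholesterol and lipid synthesis, progesterone and glucocorticoid response) had an unadjusted p under 0.05. The directional test of fry passed 0 lists, and its mixed test passed 4: oestrogen response, steroid receptors and cofactors, cholesterol and lipid synthesis, and progesterone and glucocorticoid response. The score of the stromal markers differed by -0.97 between the stages, in the same direction as the 12 other lower lists, whose scores differed by -1.89 (cell cycle) to -0.33 (oxidative phosphorylation). Of the 10 ways to split the 6 libraries into 3 and 3, the real one included, 6 gave at least 15 lists. Only 7 of the 15 kept their call without each library in turn: 12 did without post-ovulatory replicate 1, post-ovulatory replicate 2 or early luteal replicate 2, 14 without post-ovulatory replicate 3 or early luteal replicate 1, and 10 without early luteal replicate 3.

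Cholesterol and lipid synthesis fell as a list, with 26 of 27 members lower in early luteal tissue and a median log2 fold change of -1.32 (limma camera, adjusted p = 1.49e-29; adjusted p = 0.385 with an estimated correlation). No member passed over all genes in edgeR, whereas 16, all lower, passed when adjusted over the list alone, and DESeq2 called 12 of the 27 over all genes. SQLE, the squalene epoxidase of sterol synthesis, stood at 11.4 ± 4.26 CPM (SD, n = 3) against 104 ± 36.7 CPM, a 9.10-fold lower level (log2 fold change -3.19 ± 0.40, SE). CYP51A1, the lanosterol demethylase, stood at 41.9 ± 2.12 against 135 ± 34.5 CPM (3.23-fold lower). FDPS stood at 21.0 ± 1.57 against 84.6 ± 39.6 CPM. HMGCS1 and IDI1, the most abundant members, stood at 56.9 ± 16.1 against 221 ± 115 CPM and at 42.1 ± 19.3 against 146 ± 66.6 CPM. In 22 of the 27 genes every early luteal library lay below every post-ovulatory one, where chance gives 10% in both directions together. The score of the stromal marker list moved the same way, by -0.97 between the stages.

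Genes that respond to oestrogen fell as a list, with 23 of 25 lower and a median log2 fold change of -0.53 (limma camera, adjusted p = 1.44e-05; adjusted p = 0.257 with an estimated correlation). None passed over all genes in edgeR and 2, PGR and IGF1, passed adjusted over the list alone. The score of the list differed by -0.91 between the stages, about as much as that of the stromal markers (-0.97). Library by library the 2 scores ran together only in part. Post-ovulatory replicate 2 had the highest stromal score (1.02) but the lowest oestrogen score of its stage (0.20). Early luteal replicate 2 was lowest in the oestrogen list (-0.88) and early luteal replicate 3 in the stromal one (-0.86), while early luteal replicate 1 was highest of its stage in both. PGR, the nuclear progesterone receptor, stood at 12.01 ± 2.00 CPM in early luteal and 50.6 ± 14.9 CPM in post-ovulatory tissue (log2 fold change -2.08 ± 0.34, SE). IGF1 stood at 6.26 ± 0.896 against 30.3 ± 9.71 CPM (-2.27 ± 0.38), and the nuclear receptor cofactor NRIP1 at 26.4 ± 8.03 against 52.2 ± 7.53 CPM. RERG went the other way, at 143 ± 80.3 against 55.1 ± 4.22 CPM. The oestrogen receptor gene ESR1 stood at 372 ± 119 against 532 ± 212 CPM and overlapped between the stages. OVGP1, the oviduct-specific glycoprotein of secretory cells, stood at 7302, 156 and 10688 CPM in the post-ovulatory and 292, 1017 and 2356 CPM in the early luteal replicates. Its spread within a stage exceeded the difference between the stages (log2 fold change -2.31 ± 1.22, SE; edgeR adjusted p = 0.711).

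Genes induced by progesterone and glucocorticoids rose as a list, with 17 of 22 higher and a median log2 fold change of 0.47 (limma camera, adjusted p = 7.30e-05; adjusted p = 0.620 with an estimated correlation). None passed over all genes in edgeR and 6, all higher, passed adjusted over the list alone. The scores of the list were -0.42, -0.058 and -0.41 in post-ovulatory and 0.28, -0.018 and 0.62 in early luteal replicates 1, 2 and 3, a gap of 0.040 between the nearest libraries. Immediate early genes, which respond to tissue handling, rose too (median 0.53) and were likewise highest in early luteal replicate 3, with scores of -0.15, 0.28 and -0.81 in post-ovulatory and -0.37, 0.062 and 0.99 in early luteal replicates. SULT1E1, the oestrogen sulfotransferase, stood at 10.6 ± 5.74 CPM in early luteal tissue, from 361 counts, and at 0.183 ± 0.160 CPM in post-ovulatory tissue, from 6 counts, so the size of its fold change is poorly determined (log2 fold change 6.05 ± 1.16, SE). The insulin receptor substrate IRS2 stood at 84.7 ± 7.37 against 32.4 ± 7.57 CPM, the transcription factor FOXO1 at 72.5 ± 22.6 against 35.3 ± 6.84 CPM and the prolactin receptor PRLR at 15.4 ± 11.9 against 3.12 ± 0.732 CPM. FKBP5, a chaperone of steroid receptors, stood at 255 ± 135 against 82.4 ± 36.1 CPM and overlapped between the stages because early luteal replicate 1 (100.03 CPM) lay below post-ovulatory replicate 1 (117.6 CPM). NR2F2 stood at 212 ± 41.7 against 119 ± 17.3 CPM. Without post-ovulatory replicate 2 the list median was 0.91 and without early luteal replicate 3 it was 0.28, both past the threshold (camera, adjusted p = 9.85e-05 and 0.00581).

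Endoplasmic reticulum chaperones fell as a list, with 26 of 30 lower and a median log2 fold change of -0.43 (limma camera, adjusted p = 2.85e-07; adjusted p = 0.794 with an estimated correlation). None passed over all genes in edgeR and 5, all lower, passed adjusted over the list alone. HYOU1 stood at 44.5 ± 9.58 against 152 ± 42.3 CPM, the calcium-binding chaperone CALR at 497 ± 56.4 against 1504 ± 632 CPM, MANF at 46.9 ± 9.39 against 147 ± 68.6 CPM and CRELD2 at 5.84 ± 3.01 against 29.1 ± 20.5 CPM. The abundant chaperones HSP90B1 (1728 ± 813 against 2275 ± 790 CPM) and HSPA5 (578 ± 269 against 762 ± 287 CPM) overlapped between the stages. Heat shock chaperones fell too, with 18 of 20 lower and a median of -0.37 (limma camera, adjusted p = 0.00206; adjusted p = 0.794 with an estimated correlation). In edgeR 0 passed over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05. STIP1 stood at 98.2 ± 20.8 against 230 ± 78.6 CPM, DNAJA1 at 219 ± 40.7 against 573 ± 322 CPM and HSPA8 at 654 ± 345 against 1569 ± 695 CPM. The most abundant, HSP90AA1 and HSP90AB1, stood at 3495 ± 847 against 4242 ± 1044 CPM and at 1088 ± 220 against 1730 ± 268 CPM. Without early luteal replicate 3 the adjusted p of the heat shock list was 0.0637 (camera), and its median was -0.23 without post-ovulatory replicate 1 and -0.63 without early luteal replicate 2.

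Markers of fibroblasts and stroma fell as a list, with 11 of 13 lower and a median log2 fold change of -0.76 (limma camera, adjusted p = 0.000269; adjusted p = 0.759 with an estimated correlation). None passed over all genes in edgeR and 3, all lower, passed adjusted over the list alone: COL1A1 (110 ± 22.5 against 426 ± 215 CPM), COL3A1 (169 ± 32.1 against 493 ± 235 CPM) and PI16 (0.793 ± 0.284 against 5.33 ± 3.11 CPM). DCN, a stromal proteoglycan, stood at 258 ± 18.1 against 349 ± 59.8 CPM, a 1.35-fold lower level. The list median was -0.36 without post-ovulatory replicate 2, -1.20 without early luteal replicate 1 and -0.44 without early luteal replicate 3, each past the threshold (camera, highest adjusted p = 0.0321). Fibrillar collagens and matrix, which share COL1A1, COL3A1 and other genes with the stromal list, fell as well, with 22 of 29 lower and a median of -0.53 (limma camera, adjusted p = 0.00102; adjusted p = 0.759 with an estimated correlation). Of its genes, 4 passed adjusted over the list alone, 3 lower and 1 higher, and 0 over all genes (edgeR). SPARC stood at 137 ± 44.04 against 322 ± 30.2 CPM and FBLN1 at 423 ± 149 against 523 ± 93.5 CPM. The matrix protein gene TNC was the higher one, at 73.6 ± 6.03 against 37.8 ± 7.66 CPM.

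Basement membrane genes fell by the same test, with 15 of 18 lower and a median of -0.26 (limma camera, adjusted p = 0.0214; adjusted p = 0.794 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone (edgeR, 1 at an unadjusted p under 0.05). COL15A1 stood at 119 ± 75.5 against 247 ± 14.2 CPM, LAMC1 at 89.4 ± 8.07 against 132 ± 21.3 CPM and HSPG2 at 224 ± 163 against 247 ± 64.9 CPM. The median was -0.57 without early luteal replicate 1, and the call was lost without post-ovulatory replicate 2 (camera, adjusted p = 0.124, median -0.21) and without early luteal replicate 2 (adjusted p = 0.177, median -0.14).

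Markers of endothelial cells and of T and NK cells passed camera but rested on single libraries. Endothelial markers had a median of -0.60, with 13 of 15 lower (limma camera, adjusted p = 0.0379; adjusted p = 0.821 with an estimated correlation). Their scores were -0.10, 1.13 and 0.35 in post-ovulatory and 0.45, -1.82 and -0.02 in early luteal replicates 1, 2 and 3. FLT1 stood at 6.53 ± 1.43 against 19.7 ± 11.7 CPM, PLVAP at 17.7 ± 11.2 against 51.1 ± 12.6 CPM and PECAM1 at 24.2 ± 10.4 against 51.6 ± 31.4 CPM. EMCN and KDR, the most abundant, stood higher in early luteal tissue, at 306 ± 112 against 211 ± 5.85 CPM and 90.0 ± 17.9 against 63.5 ± 21.9 CPM. The endothelial call was lost without post-ovulatory replicate 2 (adjusted p = 0.562, median -0.06), without early luteal replicate 2 (0.215, median -0.37) and without early luteal replicate 3 (0.0881, all camera). It was also lost with library totals alone (0.0507) and with the replicate number as a block (0.0766, both camera). The endothelial median was -1.09 without early luteal replicate 1. T and NK cell markers had a median of -0.29, with 20 of 24 lower (limma camera, adjusted p = 0.0379; adjusted p = 0.863 with an estimated correlation). Their scores were 0.55, 1.09 and -0.04 in post-ovulatory and 1.26, -1.75 and -1.11 in early luteal replicates. CD2 stood at 5.59 ± 6.54 against 11.3 ± 5.88 CPM, CD247 at 13.99 ± 6.56 against 15.8 ± 1.44 CPM, and KLRK1 at 10.4 ± 9.97 against 9.76 ± 3.70 CPM. CD4, GZMA and NCR1 lay at 5.05 CPM or less in every library. That call was lost without post-ovulatory replicate 2 (adjusted p = 0.271, median -0.18), early luteal replicate 2 (0.303, median -0.13) or early luteal replicate 3 (0.528, median -0.05, all camera), and the median was -0.45, -0.62 and -2.20 without post-ovulatory replicate 1, post-ovulatory replicate 3 and early luteal replicate 1. In both marker lists 0 genes passed over all genes or adjusted over the list alone (edgeR), with 2 endothelial and 0 T and NK cell markers at an unadjusted p under 0.05.

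Cell cycle genes fell as a list, with 47 of 47 lower and a median log2 fold change of -2.47 (limma camera, adjusted p = 1.52e-14; adjusted p = 0.794 with an estimated correlation). The list was high in 1 library, post-ovulatory replicate 1, with a score of 2.81. Post-ovulatory replicates 2 and 3 and early luteal replicate 1 lay close together (0.027, -0.0039 and -0.028). Early luteal replicates 2 and 3 were lower (-1.49 and -1.31). Without post-ovulatory replicate 1 the median was -0.80 (camera, adjusted p = 0.000160). None passed over all genes or adjusted over the list alone (edgeR), with 27 at an unadjusted p under 0.05. The replication helicase genes MCM4, MCM3 and MCM6 stood at 107, 116 and 129 CPM in post-ovulatory replicate 1, against 23.5, 70.2 and 29.8 CPM in replicate 2 and 18.1, 29.3 and 20.6 CPM in replicate 3. Their early luteal means were 8.48 ± 4.00, 20.3 ± 7.90 and 14.5 ± 1.15 CPM. CDT1, a licensing factor of replication, stood at 17.5 CPM in post-ovulatory replicate 1 and at 0 to 3.61 CPM elsewhere. The most abundant members, HMGB2 and RRM1, stood at 356 and 268 CPM in post-ovulatory replicate 1 and between 104 and 177 CPM in the other libraries.

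Of the 4 other lists that passed, 3 fell and 1 rose. Interferon response genes fell, with 31 of 39 lower and a median of -0.44 (limma camera, adjusted p = 0.000514; adjusted p = 0.821 with an estimated correlation). MX1 stood at 139 ± 26.4 against 271 ± 113 CPM, BST2 at 17.0 ± 8.62 against 40.7 ± 22.8 CPM, XAF1 at 34.7 ± 8.38 against 54.9 ± 7.26 CPM and IFI6, the most abundant, at 450 ± 256 against 610 ± 312 CPM. Without post-ovulatory replicate 1 that call was lost (camera, adjusted p = 0.161, median -0.21), and without early luteal replicate 1 the median was -0.66. Nuclear genes of oxidative phosphorylation fell, with 35 of 42 lower and a median of -0.23 (limma camera, adjusted p = 0.0117; adjusted p = 0.821 with an estimated correlation). COX7A2 stood at 31.2 ± 3.83 against 54.1 ± 20.9 CPM, NDUFA1 at 36.6 ± 11.3 against 60.2 ± 10.9 CPM and ATP5PB, the most abundant, at 239 ± 77.7 against 271 ± 106 CPM. That call was lost without post-ovulatory replicate 1 (camera, adjusted p = 0.355, median -0.07) and without early luteal replicate 1 (0.223, median -0.12), and the median was -0.35 without post-ovulatory replicate 2. Antioxidant enzymes fell, with 19 of 24 lower and a median of -0.29 (limma camera, adjusted p = 0.0410; adjusted p = 0.821 with an estimated correlation). GPX7 stood at 5.92 ± 1.80 against 17.5 ± 6.47 CPM, PRDX6 at 132 ± 47.8 against 221 ± 27.6 CPM, PRDX1 at 163 ± 58.7 against 271 ± 150 CPM and SOD1 at 208 ± 138 against 173 ± 56.3 CPM. That call was lost without post-ovulatory replicate 1 (camera, adjusted p = 0.397, median -0.18), without early luteal replicate 3 (0.124) and with the replicate number as a block (0.0517). Immediate early genes, which are induced within minutes of a stimulus such as tissue handling, rose, with 19 of 25 higher and a median of 0.53 (limma camera, adjusted p = 0.0117; adjusted p = 0.821 with an estimated correlation). ATF3 stood at 27.2, 260 and 239 CPM in early luteal and at 61.0, 66.6 and 16.3 CPM in post-ovulatory replicates, and JUN and FOS at 324 ± 133 against 189 ± 41.2 CPM and 245 ± 161 against 99.0 ± 73.2 CPM. Their call was lost without post-ovulatory replicate 3 (camera, adjusted p = 0.126) and without early luteal replicate 3 (0.564, median 0.15). In these 4 lists 0 genes passed over all genes or adjusted over the list alone (edgeR), with 3, 2, 3 and 1 genes at an unadjusted p under 0.05 in the direction of the list.

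**Figure D3:**
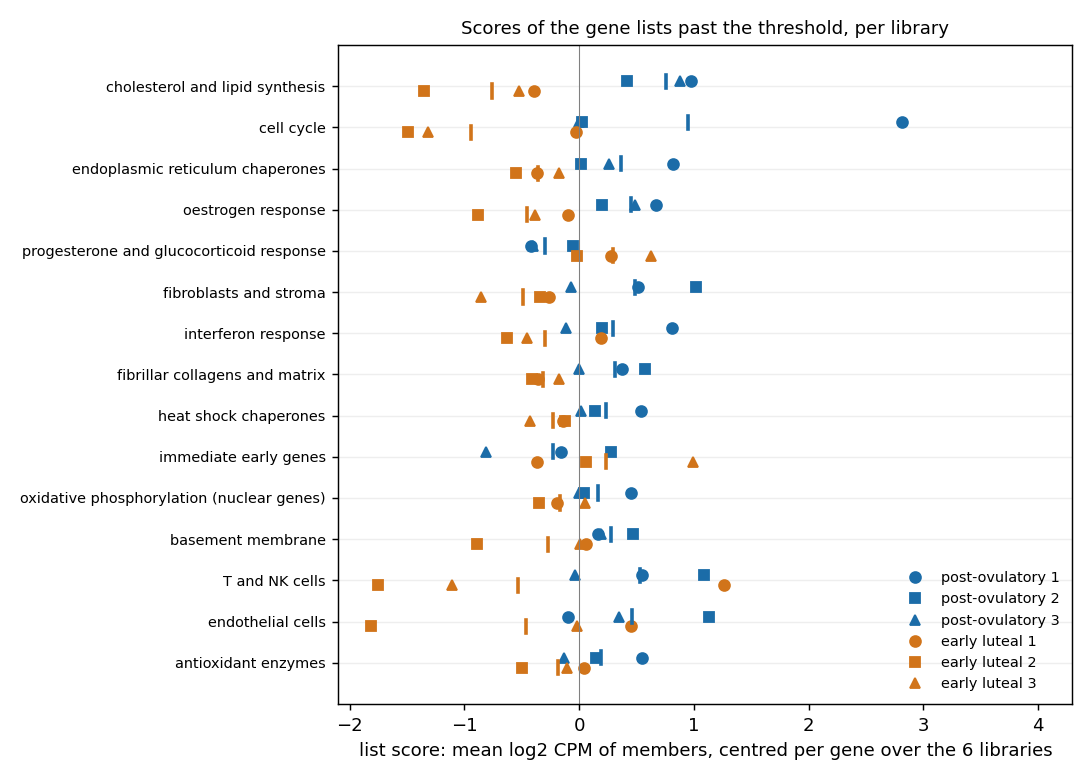
Scores of the 15 lists past the threshold in each library: the mean over members of log2 CPM, centred per gene over the 6 libraries, with bars for the group means, colours for the stage and symbols for the replicate. Cholesterol and lipid synthesis separates the stages by 0.81 between the nearest libraries, and the cell cycle score of 2.81 belongs to post-ovulatory replicate 1 alone.

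Of the fixed panel, the regulator of motile cilia FOXJ1 stood at 301 ± 192 CPM in early luteal and 428 ± 227 CPM in post-ovulatory tissue (edgeR adjusted p = 0.860). OXTR, the oxytocin receptor, stood at 1.12 ± 1.49 against 0.883 ± 0.133 CPM and PTGS2, a prostaglandin synthase, at 1.61 ± 1.26 against 1.88 ± 0.703 CPM (edgeR adjusted p = 0.941 and 0.945). HSPA5 had an adjusted p of 0.844 and ESR1 one of 0.779 in the same test. The levels of these genes overlapped between the stages.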

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

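The fits on genes with a symbol alone and without robust estimates were chosen after seeing the data. Results kept their direction more often than their call. All 10 genes with the lowest p and 76 of 88 named genes kept their sign under each of 17 settings, and the 15 lists kept theirs under each setting tried, 14 of them keeping their call under the 3 other scalings. The 10 genes and the 15 lists were chosen by their p in these same libraries, which made a kept sign likely. Other scalings moved the median of all genes by less than 0.1 on the log2 scale. The number of genes past the threshold, 0 in edgeR, was also 0 with each library left out (603 to 2138 genes at an unadjusted p under 0.05), under other scalings and at thresholds of 0.01 and 0.1. It was 8 with no filter on low counts, 9 with sample quality weights in limma voom and 175 in DESeq2, and the same numbers had at least a 2-fold change; the cause was not tested. Of the added settings, genes with a symbol alone and no robust estimates each gave 0. Lists past the threshold numbered 15, 24 with no filter, 0 with an estimated correlation, 0 by fry and 10 to 23 with 1 library left out. No label says that libraries sharing a number pair. Deviations of same-numbered libraries from their group means correlated at 0.05, -0.08 and 0.13 across genes. Those of differently numbered libraries correlated at -0.16 to 0.06. With 3 libraries per stage these values neither show nor exclude a pairing. With the replicate number as a block, 0 genes and 15 lists passed; endothelial cells (adjusted p = 0.0766) and antioxidant enzymes (0.0517) lost their call by camera, and MHC class II (0.0326) and ciliogenesis regulators (0.0231) gained one. Under the block the log2 fold changes of OXTR (-0.57) and KLRK1 (-0.32) and the medians of the lists of Hedgehog signalling (0.19), cumulus and granulosa cells (-0.17), steroid metabolism enzymes (-0.0744) and secretory epithelium (-0.27) turned sign; the cause was not tested. Other values that turned sign belonged to genes and lists not past the threshold, and the cause was not tested. In limma voom, OXTR was -0.50 and KLRK1 -0.11 (log2). With sample quality weights FOXJ1 was 0.0271, OXTR -1.18, IFI6 0.0810, CD4 0.31, KLRK1 -0.34 and SOD1 -0.23. With no filter the lists of adipocytes, cumulus and granulosa cells and motile cilia structure had medians of -0.18, -0.0405 and -0.0213. With a filter of 1 CPM, pericytes had 0.30 and mucosal defence 0.00172. Ribosomal proteins had 0.00121 with DESeq2 size factors and 0.0318 with upper quartile scaling, embryotrophic signalling 0.00116 with the latter, and neutrophils and mast cells 0.00226 with library totals alone. With 1 library left out, log2 fold changes ranged as follows: OXTR -1.76 to 0.90, PTGS2 -1.04 to 0.18, HMGB2 -0.82 to 0.22, RRM1 -0.63 to 0.14, ATP5PB -0.48 to 0.17, HSPG2 -0.73 to 0.33, CD247 -0.60 to 0.0751, KLRK1 -1.04 to 0.52, SOD1 -0.43 to 0.53, smooth muscle cells -0.22 to 1.11, motile cilia structure -0.14 to 0.26, pericytes -0.67 to 0.0344, steroid metabolism enzymes -0.22 to 0.12, adipocytes -0.78 to 0.34, contraction receptors and channels -0.40 to 0.17, Hedgehog signalling -0.31 to 0.19, mitochondrially encoded genes -0.90 to 0.0427, steroid receptors and cofactors -0.48 to 0.0748, cumulus and granulosa cells -0.35 to 0.50, embryotrophic signalling -0.32 to 0.16, neutrophils and mast cells -0.96 to 0.33, mucosal defence -0.54 to 0.0742, secretory epithelium -0.39 to 0.29, ribosomal proteins -0.0969 to 0.12. With totals of 7370723 and 8342520 counts, the 2 shallowest libraries put 3 counts at 0.379 and 0.406 CPM, which limits statements on genes as low as OXTR, PTGS2 and CD4.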

Other observations

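Tests chosen only after the result was seen were the splits for the gene count and for the sterol score, the tests of the sterol list against early luteal replicate 2, depth and stromal share, the depth and wrong-label tests of early luteal replicate 2, and the lymphocyte and multiciliation tests. Several gene groups differed more between libraries of one stage than between the stages. Each list of this paragraph missed the threshold with all 6 libraries, and leaving out 1 of them gave several a call by limma camera. Structural genes of motile cilia had a median log2 fold change of 0.04 (camera, adjusted p = 0.552; medians from -0.14 to 0.26 with 1 library left out) and passed as higher without post-ovulatory replicate 1 (0.00434). Ciliogenesis regulators had a median of -0.25 (camera, adjusted p = 0.131; -0.40 to -0.04), with a score of 1.42 in post-ovulatory replicate 1 and 0.20 or less in the other 5 libraries. They passed as lower without post-ovulatory replicate 2 (0.000134) or 3 (0.0326), while without post-ovulatory replicate 1 the adjusted p was 0.858. Markers of the secretory epithelium had no stable direction: the median was 0.09 and the mean -0.24, camera placed them lower (adjusted p = 0.978), and medians ran from -0.39 to 0.29 with 1 library left out. Smooth muscle markers scored -1.56, 0.50 and 1.29 in early luteal replicates 1, 2 and 3 (median 0.61, camera adjusted p = 0.186). They passed as higher without early luteal replicate 1 (2.17e-07, median 1.11) or post-ovulatory replicate 2 (0.0224, median 0.94), and their median was -0.22 without early luteal replicate 3. Markers of B and plasma cells scored 1.36 in post-ovulatory and 1.24 in early luteal replicate 1 (camera, adjusted p = 0.302; medians from -1.25 to -0.02) and passed as lower without early luteal replicate 1 (0.0322) or post-ovulatory replicate 3 (0.0326). Those of macrophages and dendritic cells (adjusted p = 0.183; -1.12 to -0.14) passed without the same libraries (0.00106 and 0.00426). WNT signalling (median -0.27, camera adjusted p = 0.0624; -0.34 to -0.06) passed without post-ovulatory replicate 1 (0.0325) or 3 (0.0326). MHC class II (median -0.44, adjusted p = 0.0631; -1.53 to -0.11) passed without early luteal replicate 1 (2.25e-05) or post-ovulatory replicate 3 (0.0102), and the adjusted p was 0.509 without early luteal replicate 3. Mitochondrially encoded genes, a sign of RNA quality, had a median of -0.26 (camera, adjusted p = 0.226) and passed as lower without early luteal replicate 2 (2.02e-09, median -0.90) or post-ovulatory replicate 2 (0.0466, median -0.43), whereas without early luteal replicate 1 the median was 0.0427. Their scores were 0.54, -0.22 and 0.20 in post-ovulatory and -0.61, 0.73 and -0.64 in early luteal replicates 1, 2 and 3. Without post-ovulatory replicate 3, hyaluronan metabolism (camera, adjusted p = 0.0131), matrix proteases and inhibitors (0.0297), cytokines and chemokines (0.0171) and complement and coagulation (0.0182) passed as lower, the last 2 also without early luteal replicate 1 (0.00759 and 0.0108), and glycolysis passed as lower without post-ovulatory replicate 2 (0.0388). Ribosomal protein genes had a median of -0.01 (camera, adjusted p = 0.978), which turned to 0.00121 with DESeq2 size factors and 0.0318 with upper quartile scaling.

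Sets too small to test held the following highest levels. WT1 of the mesothelial set reached 468 CPM in early luteal replicate 3, ODF2 of the sperm set 171 CPM in post-ovulatory replicate 1, and HBB of erythrocytes 166 CPM in early luteal replicate 1. GDF9 of the oocyte set reached 37.2 CPM in early luteal replicate 1, TUBB3 of nerve 20.7 CPM and GP9 of platelets 9.31 CPM, both in post-ovulatory replicate 1. A high level of 1 member does not show that its cell type was present. PRM1, PRM2, TNP1 and ODF1 of the sperm set and ZP3, NOBOX and ZAR1 of the oocyte set had 0 counts in every library. ZP2 of the oocyte set had 85, 3 and 193 counts in post-ovulatory and 4, 0 and 2 in early luteal replicates 1, 2 and 3. It was filtered out before the edgeR test and was called by DESeq2 (log2 fold change -4.92, adjusted p = 0.0105). CALB2 of the mesothelial set had at most 1 count in any library. Other members, such as SPATA18 (sperm) and UPK1B (mesothelium), had counts in every library.

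The lower sterol list in early luteal tissue is the first pattern. The 6 libraries allow 10 splits, too few for a share under 0.05. The difference of mean sterol scores was 1.52 for the stages and 0.977 for the highest other split. For lists past the threshold, 6 of the 10 splits gave at least the real 15 (highest other 21). For genes past the threshold by edgeR, the real split gave 0 and the highest other 4. At an unadjusted p under 0.05 edgeR counted 1275 genes for the real split and 117 to 935 for the other splits. DESeq2 called 175 genes for the stages and was not run on the other splits. Early luteal replicate 2 alone does not account for the pattern, since without it the lowest post-ovulatory score still lay 0.810 above the highest early luteal one. That library has the lowest score, so leaving it out could not narrow this gap. Nor does depth alone, since the shallowest library, post-ovulatory replicate 2, scored 0.810 above the higher of the deeper early luteal replicates 1 and 3. Both statements rest on the same gap and are not separate evidence. A lower share of stromal cells could contribute and cannot be told apart from lower expression within cells. The stromal marker score changed in the same direction, by -0.97 against -1.52 for the sterol list. Library by library the 2 scores ran together only in part. Post-ovulatory replicate 2 had the highest stromal score (1.02) but the lowest sterol score of its stage (0.41). Post-ovulatory replicate 3 and early luteal replicate 1 were close in stromal score (-0.07 and -0.26) but not in sterol score (0.88 and -0.40). Among early luteal libraries, replicate 1 was highest in both. The stage itself, with the change in steroid hormones that it brings, stays open and was not tested.

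Early luteal replicate 2 stood apart from the other libraries. Depth argues little for it, since its median absolute deviation from the other libraries of its stage was 2.12 times that of the shallower post-ovulatory replicate 2. Its sterol score lay 1.77 below the lowest post-ovulatory one, where a wrong stage label would place it near that stage. The sterol list was chosen with this library counted as early luteal, though it passed without it too (camera, adjusted p = 5.48e-35). The library also scored below early luteal replicates 1 and 3 (-1.36 against -0.40 and -0.52). A score outside both stages does not settle the label. A candidate explanation is a bias by gene span: across 11911 genes its deviation correlated with genomic span (Spearman rho 0.32, against -0.0380 to 0.0128 in the post-ovulatory libraries, and -0.25 and -0.26 in early luteal replicates 1 and 3, whose reference includes this library), from a median of -0.91 in the shortest to 0.21 in the longest span group (median spans 6.45 and 141 kb). In this library 367 genes had 0 counts despite at least 1 CPM in each other library, against 5 in post-ovulatory replicate 2. The share of mitochondrially encoded counts was highest in this library (7.54%, against 3.47% to 6.92% in the others). So was the share of the 10 most abundant genes (17.7% against 11.3% to 13.1%). RNA or library quality as a cause was not tested. GC content was not analysed here, and no biological explanation was tested.

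Post-ovulatory replicate 1 was high in cell cycle genes, with 45 of 47 over 2-fold above the other libraries of its stage. Proliferating lymphocytes stay open. Early luteal replicate 1 had a higher lymphocyte score (1.25 against 0.956) with a cell cycle score 2.84 lower. Post-ovulatory replicate 2 had a lymphocyte score of 0.817, with a cell cycle score of 0.0273. In each stage, however, the library with the highest lymphocyte score also had the highest cell cycle score (-0.0280 in early luteal replicate 1). Against the other libraries of its stage, 28 of 47 genes were over 2-fold in early luteal replicate 1 and 0 of 47 in post-ovulatory replicate 2. These counts cannot be compared between the stages. The reference of post-ovulatory replicate 2 includes post-ovulatory replicate 1, and that of early luteal replicate 1 is the low early luteal replicates 2 and 3 (scores -1.49 and -1.31). These markers do not show whether lymphocytes divide. Cells entering multiciliation, which use cell cycle regulators to amplify centrioles, are another candidate source: 9 regulators, all from the ciliogenesis list already known to score 1.42 there, had a median log2 excess of 1.16 in that library. MCIDAS stood at 59.2 CPM against 0.379 and 4.51, CDC20B at 52.9 against 0.253 and 2.85 and CCNO at 95.8 against 1.39 and 6.49 CPM in the other post-ovulatory replicates, whereas RFX3, GMNC, TP73 and RFX2 were less than 2-fold higher. Whether such cells belong to the post-ovulatory stage or to this sample is not answered by 1 library.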
